A study of Mus musculus with 9 samples.

How the data were processed

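Poly-A RNA of 9 MS1 samples in 3 groups was sequenced by the authors, per the labels, after column extraction, DNase treatment, preparation with a stranded kit and an Illumina HiSeq run. Lentiviral vectors of the pCDH family delivered the constructs. Per the submitters' processing notes, the reads were handled with bcl2fastq, FastQC, STAR, featureCounts and edgeR on the mouse build mm10, with versions and settings not given in the sources used here. Gene values are on the GENCODE vM4 annotation, per the deposited file names, and an iGenomes gene table served as an alternative. Whether counting used strand was not given, so overlapping and antisense genes are not told apart.

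The gene values are a deposited signal, reads per gene divided by a scaled library size, which the authors name CPM. The sums of a library ranged from 973009 to 1034030 CPM and were not equal between libraries, which is how edgeR's library factors appear. Because every value was a whole multiple of the value of a single read (100% of values within a tolerance of 0.01), whole reads were recovered, 22817562 to 35491338 per library. The deposited TPM values, scaled for transcript length by the authors, entered as an alternative unit. The authors' log2 fold changes and p-values (false discovery rates) from the deposited comparison table are quoted only as theirs. The deposited junction files hold counts of uniquely and multiply mapped reads across each intron as STAR writes them, 6410070 to 9889541 unique junction reads per library. The deposited transcript tables were not used, since reads are counted there for every transcript they overlap. Gene symbols, transcript lengths, exon numbers and coordinates came from GENCODE vM21 on GRCm38, the same build as mm10, and 23439 of 23744 gene identifiers had a symbol and 305 did not. No column of per-sample values was left unassigned.

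Groups and replicate numbers were taken from the sample titles. The main test was limma-trend (limma 3.58.1 in R 4.3.3; lmFit and eBayes with trend and robust settings) on log2(CPM + 0.5), with all 9 libraries in a single fit of 6 residual degrees of freedom and 3 contrasts. Genes with at least 0.5 CPM in at least 3 libraries were tested, 13346 of 23744, with Benjamini-Hochberg adjustment and a threshold of 0.05. The median standard error of a log2 fold change was 0.138, and fold changes on this scale understate the change of low genes. The design assumed CPM. The deposited values were entered as signal, since the sums differ between libraries, and the test stayed as planned. Low-count genes with 1 to 3 reads in a group are given by those reads, some with a ratio and its 95% counting interval. Those with 0 reads are given as a bound against 3 reads per library.

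The 26 gene lists (575 entries, 544 found in the gene table, 5 of them under another symbol) were fixed before the data were examined, as were the groups, the tests, the other settings and the rule for naming genes. Each was tested with camera at a preset correlation of 0.01, two-sided, adjusted over the lists of a comparison, and again with an estimated correlation. With the preset correlation 13, 10 and 13 lists passed in TAZ4A against control, TAZ-CAMTA1 against control and TAZ-CAMTA1 against TAZ4A, and with an estimated correlation 5, 4 and 4 passed. Those that held were the YAP/TAZ-TEAD, endothelial, interferon, NF-kB and cholesterol lists in the first, the cell cycle, NF-kB, cholesterol and glycolysis lists in the second, and the endothelial, cell cycle, interferon and NF-kB lists in the third. At the preset correlation, other divisions of the 6 samples of a comparison, which mix its groups, passed up to 10, 11 and 8 lists. The fry test, which asks only whether a list's genes move one way on balance, passed for 19, 17 and 19 lists, including all those that camera called. The named genes are, per comparison, the 10 with the largest rise and the 10 with the largest fall among called genes with at least 5 CPM in the higher group, no overlap between the groups and a proper name. To these come Wwtr1, Camta1, Yap1 and the TEAD genes, and up to 2 called members in each direction of every list. All named genes called in a comparison had samples that did not overlap between the groups (89, 90 and 94 genes). For the largest rises and falls the rule itself required this. Counts of list members were recomputed without TAZ-CAMTA1 replicate 2, and are given where they differ by over 1.5 times. Without other single libraries the list tests were recomputed, but the members' counts only for the interferon list without each TAZ4A library.

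Junction reads were compared with a two-sided exact permutation test, which cannot go below 0.1 for 3 against 3 samples. The alternatives were pseudocounts of 0.1 and 2, no filter and a minimum of 2 CPM, CPM rescaled to the same sum in every library, quantile normalization, TPM, the iGenomes table, a fit of the compared 6 samples alone, the replicate number as a block, a log2 fold change of at least 1, edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0 on the recovered reads, and each library left out in turn. Library quality weights were added after the data were seen. The test was checked on simulated reads with 200 changed genes, a share of which was recovered at each fold. Baseline means and spread per gene were the same for every comparison, and no library was made to stand apart. Differences in the rates between comparisons may therefore reflect the draw. For TAZ4A against control (12778 genes) 26.9%, 80.6% and 89.4% of genes changed by a factor of 1.5, 2 and 4 were recovered, and 3.60% of calls were unchanged genes. For TAZ-CAMTA1 against control (12769 genes) these were 34.3%, 74.6%, 95.5% and 5.30%, and for TAZ-CAMTA1 against TAZ4A (12775 genes) 17.9%, 76.1%, 89.4% and 1.55%. Tables and figures used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.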

Results

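MS1, an endothelial cell line from the mouse pancreas, was profiled by mRNA sequencing in 3 groups of 3 samples each. Control cells carried a puromycin lentiviral vector, and the other groups stably expressed TAZ4A or TAZ-CAMTA1 from the same vector family. TAZ, the product of Wwtr1, is a transcriptional co-activator that the Hippo pathway restrains and that acts through the TEAD family of DNA-binding proteins. TAZ4A is a mutant with Hippo kinase sites changed from serine to alanine. TAZ-CAMTA1 is the fusion protein of epithelioid hemangioendothelioma, a vascular cancer, and joins the first part of TAZ to the last part of CAMTA1, a transcription activator that binds calmodulin. The reads assigned to genes, recovered from the deposited values, numbered 22817562, 35491338 and 34099031 in control replicates 1 to 3. They numbered 32886933, 34637837 and 33200105 in the libraries labelled TAZ4A and 33766147, 30527570 and 23763823 in TAZ-CAMTA1. In a single library a count of 0 allows a level of up to 0.0849 to 0.134 CPM, taken as 3 reads, which covers counting error only. Expression values below are deposited CPM as mean ± SD over n = 3 samples, and log2 fold changes are on the log2(CPM + 0.5) scale with their standard error. A gene is said to have risen or fallen only where its adjusted p from limma was under 0.05. The labels do not say that the samples of a group came from separate cultures, so p-values rest on spread between samples that may be technical. That spread is pooled over all 9 libraries, and is not that of the compared groups alone. With only the 6 samples compared, 7535 genes were called in TAZ4A against control in place of 3225. The TAZ-CAMTA1 comparisons went the other way, with 2527 in place of 4140 against control and 3430 in place of 4890 against TAZ4A.

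TAZ-CAMTA1 replicate 2 stood apart from the other 8 libraries. Its log2 correlation across genes was 0.968 and 0.967 with the other TAZ-CAMTA1 samples, while every other replicate pair of a group reached at least 0.996. Ribosomal protein genes took 4.23% of its reads, against 1.95% to 2.25% in the other libraries. Reads mapped to several places made up 30.6% of its junction reads (95% Wilson interval 30.6% to 30.6%), against 20.8% to 22.2% elsewhere, and the read-weighted median transcript length was 3063 nt against 3585 to 3685 nt.

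**Figure D1:**
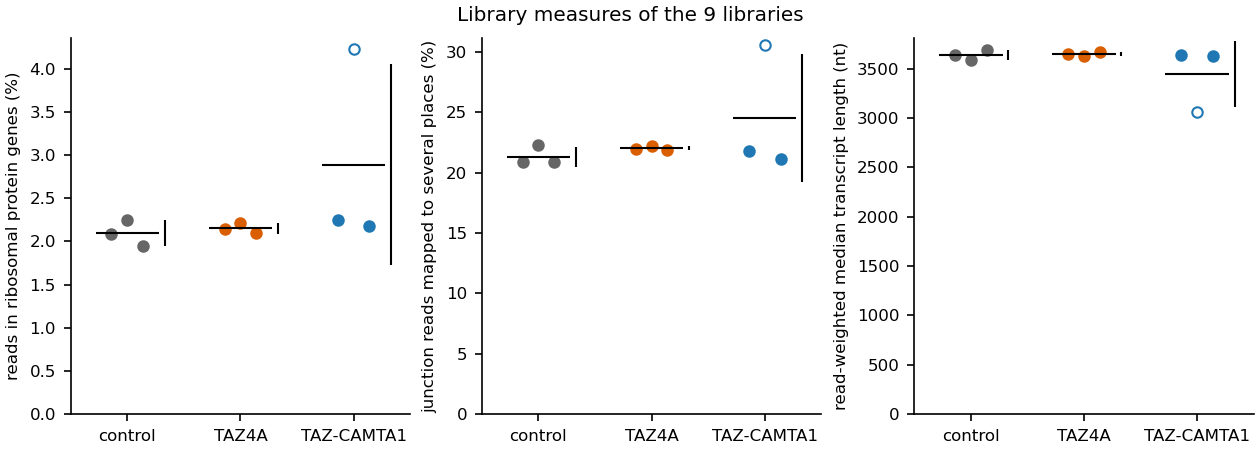
Properties of the 9 libraries by group, each point a library, with TAZ-CAMTA1 replicate 2 as an open circle, the black bar the group mean and the vertical line the SD. TAZ-CAMTA1 replicate 2 had 4.23% of reads in ribosomal protein genes and 30.6% multiply mapped junction reads, above all other libraries.

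The genes carried by the constructs were examined first. Camta1 (ENSMUSG00000014592.15, mm10 chromosome 4, 150917322 to 151861876) stood at 4.90 ± 0.825 CPM in control, 5.49 ± 0.267 CPM in the libraries labelled TAZ4A and 13.5 ± 0.45 CPM in TAZ-CAMTA1. It was higher in all 3 TAZ-CAMTA1 samples than in control (log2 fold change 1.39 ± 0.12, adjusted p = 6.4e-05) and than in TAZ4A (log2 fold change 1.23 ± 0.12, adjusted p = 7.8e-05). It did not pass the test between TAZ4A and control (log2 fold change 0.16 ± 0.12, adjusted p = 0.39). Spliced reads across Camta1 exons 9 to 24, introns between 151062856 and 151143715, numbered 236 in TAZ-CAMTA1 and 0 in the other 6 libraries. They were uneven along this part. Exons 22 to 23 held 39, 22 and 23 reads in TAZ-CAMTA1 replicates 1 to 3, and exons 23 to 24 held 40, 21 and 14. Exons 10 to 11 held 0, 0 and 1. No annotated junction between exons 12 and 14 or between exons 16 and 22 held a unique read in any library. Relative to the unique junction reads of each library the 236 reads are 9.77 ± 3.10 RPM. The mean was at least 20.9-fold higher than 3 reads per control library and at least 30.7-fold higher than 3 reads per TAZ4A library (exact permutation p = 0.1, two-sided, the smallest that 3 against 3 samples allow). The lowest TAZ-CAMTA1 library, replicate 2 with 51 such reads, was at least 14.7-fold higher than the control floor. Across Camta1 exons 1 to 4 the values were 4.18 ± 0.886, 4.83 ± 0.418 and 7.42 ± 3.15 RPM in control, TAZ4A and TAZ-CAMTA1 (exact permutation p = 0.3 for TAZ4A and 0.1 for TAZ-CAMTA1 against control). Exons 1 to 4 were taken over several transcripts, while exons 9 to 24 are numbered on Camta1-211. The junction of exons 3 to 4 in Camta1-209 held 15, 19 and 23 unique reads in control replicates 1 to 3. It held 17, 35 and 24 in TAZ4A and 23, 44 and 15 in TAZ-CAMTA1. In Camta1-211 that junction held 0 in control and TAZ4A and 0, 1 and 0 in TAZ-CAMTA1. The values therefore do not show splicing through exons 1 to 4 of Camta1-211. The division at exon 9 was chosen after the values were seen.

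Wwtr1 (ENSMUSG00000027803.10, chromosome 3, 57455649 to 57575910) went against the label of the TAZ4A libraries. Its level was 532 ± 17.8 CPM in control and 314 ± 8.04 CPM in the libraries labelled TAZ4A, where it fell (log2 fold change -0.76 ± 0.15, adjusted p = 0.0068). The fall did not pass the threshold with deposited TPM in place of CPM (log2 fold change -0.70, adjusted p = 0.054). TAZ-CAMTA1 stood at 419 ± 93.4 CPM, which did not pass against control (log2 fold change -0.37 ± 0.15, adjusted p = 0.099) or against TAZ4A (log2 fold change 0.39 ± 0.15, adjusted p = 0.076). Without TAZ-CAMTA1 replicate 2 both did (log2 fold change -0.17, adjusted p = 0.0053, and 0.59, adjusted p = 1.5e-08). Reads across Wwtr1 exons 2 to 7, most of the coding part, were 137 ± 18.4 RPM in control, 81.1 ± 1.87 in TAZ4A and 105 ± 38.1 in TAZ-CAMTA1 (exact permutation p = 0.1 and 0.3 against control). Across exons 1 to 2, a junction in the 5′ untranslated part upstream of the start codon, they were 7.63 ± 2.00, 4.10 ± 0.524 and 5.04 ± 2.36 RPM (exact permutation p = 0.1 and 0.2). The labels do not give the species of the TAZ sequence in the constructs, and reads from a human sequence need not align to the mouse genome. Whether reads of the mouse gene include the construct's own TAZ is therefore open, and the group is called by its label throughout.

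The partners of TAZ were followed in the same way. Yap1, the paralog of Wwtr1, passed as lower in TAZ-CAMTA1 than in control (log2 fold change -0.44 ± 0.14, adjusted p = 0.038). That call was lost without control replicate 1, 2 or 3 (adjusted p = 0.0930, 0.0984 and 0.110) and without TAZ4A replicate 1, 2 or 3 (0.0658, 0.0654 and 0.0654). It was also lost with TPM (0.115) and with quantile normalization (0.0642). The call was kept without TAZ-CAMTA1 replicate 2 at -0.27 (adjusted p = 8.0e-05), and at -0.27 with library quality weights (2.5e-04). Yap1 did not pass in TAZ4A against control (log2 fold change -0.10 ± 0.14, adjusted p = 0.67) or in TAZ-CAMTA1 against TAZ4A (log2 fold change -0.34 ± 0.14, adjusted p = 0.081). The latter passed without TAZ-CAMTA1 replicate 1 (-0.44, adjusted p = 0.0374) or 2 (-0.16, 0.00413), and with quantile normalization (-0.33, 0.0459). Tead3 rose in TAZ4A (log2 fold change 1.16 ± 0.10, adjusted p = 5.9e-05) and in TAZ-CAMTA1 (log2 fold change 0.69 ± 0.10, adjusted p = 0.0013). Tead1, Tead2 and Tead4 did not pass in any comparison with CPM of all libraries at equal weight, and Tead2 passed in TAZ4A against control with TPM (0.35, adjusted p = 0.0175). With library quality weights, chosen after the data were seen, Tead1, Tead2, Tead4 and Yap1 passed in TAZ4A against control (0.46, 0.29, -0.26 and -0.10, adjusted p = 1.4e-06, 1.2e-04, 0.0019 and 0.0487). With those weights Tead1, Tead2 and Yap1 also passed in TAZ-CAMTA1 against TAZ4A (-0.32, -0.19 and -0.18, adjusted p = 1.8e-04, 0.0076 and 0.0021). Without TAZ-CAMTA1 replicate 2 Tead1, Tead2 and Tead4 passed in TAZ4A against control, at 0.47, 0.29 and -0.28, and Yap1 did at -0.10 (adjusted p = 0.0382). In TAZ-CAMTA1 against TAZ4A, Tead1 passed without TAZ-CAMTA1 replicate 1, 2 or 3, at -0.85, -0.31 and -0.84 (adjusted p = 0.0370, 7.6e-05 and 0.0426), and Tead2 without replicate 2, at -0.19 (0.00969). In TAZ-CAMTA1 against control, Tead4 passed without TAZ-CAMTA1 replicate 1 (-0.40, adjusted p = 0.0411). Tead1 there turned from -0.20 ± 0.256 to 0.16 without TAZ-CAMTA1 replicate 2 (adjusted p = 0.0143).

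**Figure D2:**
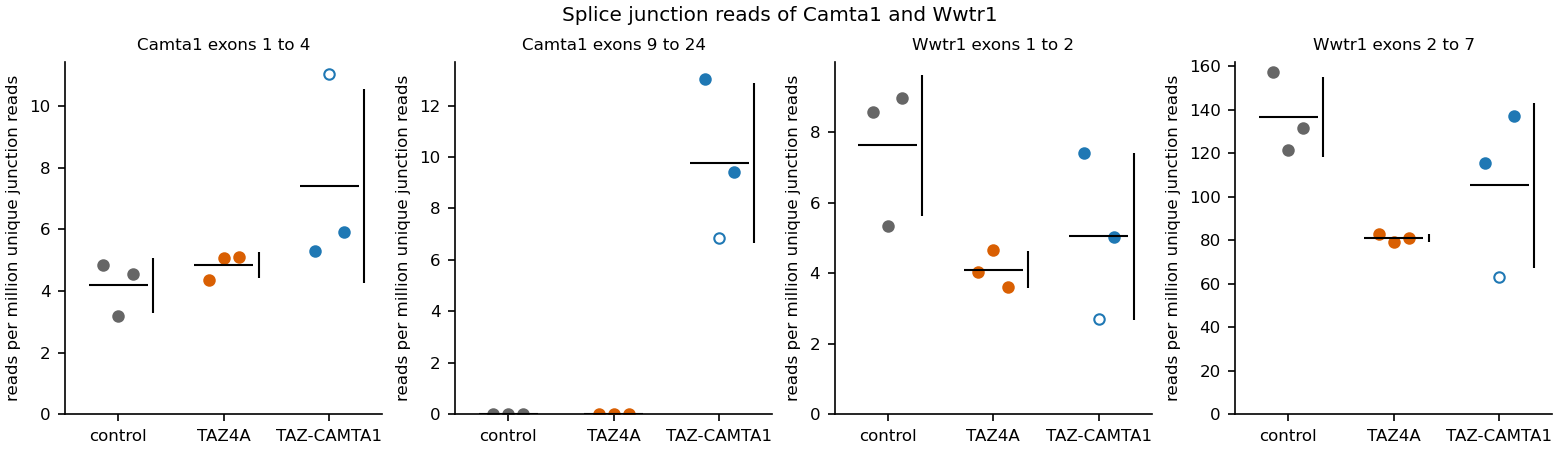
Spliced reads (RPM of the library's unique junction reads) across the 5′ and 3′ parts of Camta1 and Wwtr1, each point a library (open circle, TAZ-CAMTA1 replicate 2), with the group mean as a black bar and the SD as a vertical line. Camta1 exons 9 to 24 had 0 reads in the 6 control and TAZ4A libraries and a mean of 9.77 RPM in TAZ-CAMTA1.

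The first comparison set the libraries labelled TAZ4A against control. Interferon response, inflammatory and YAP/TAZ-TEAD target genes were higher in these libraries, and endothelial identity and cholesterol synthesis genes were lower. C3, the central complement component, rose from 1.96 ± 0.0859 to 199 ± 8.31 CPM (log2 fold change 6.34 ± 0.10, adjusted p = 1.0e-08). Ankrd1, a textbook YAP/TAZ target, rose from 30.1 ± 1.64 to 385 ± 2.15 CPM (log2 fold change 3.66 ± 0.07, adjusted p = 3.3e-08). Cxcr4, the receptor of the chemokine Cxcl12, fell from 217 ± 16.0 to 26.3 ± 0.931 CPM (log2 fold change -3.02 ± 0.09, adjusted p = 1.0e-07).

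Among named genes with at least 5 CPM in the higher group, the 10 with the largest fitted rise were C3, Lcn2, Cp, Wfdc17, Cxcl1, Siglecg, Slpi, Cxcl2, Cxcl5 and C1s1. Lcn2, an iron-sequestering protein of inflammation, rose from 3.52 ± 0.862 to 273 ± 4.89 CPM. Cp, ceruloplasmin, rose from 0.149 ± 0.0316 to 37.0 ± 0.724 CPM. Siglecg had 1 read in the control libraries together and 22.9 ± 0.199 CPM in TAZ4A (ratio 2382, 95% counting interval 357 to 78541). Slpi, a secreted protease inhibitor, likewise had 1 control read and 20.3 ± 0.867 CPM in TAZ4A (ratio 2012, 95% counting interval 316 to 69614). Cxcl5 had 3 control reads and 15.5 ± 0.902 CPM (ratio 448, 95% counting interval 153 to 2172). Wfdc17 and C1s1 had log2 fold changes of 5.76 ± 0.22 and 4.70 ± 0.15, the latter uncertain because C1s1 has a near copy. The 10 largest falls were Ttyh1, Sparcl1, Cxcr4, Rtl8a, Slco2b1, Rtl8b, Nrxn2, Cldn15, Speer4a and Fry. Sparcl1, a matricellular protein, fell from 143 ± 4.39 to 16.7 ± 1.28 CPM. Cldn15, a tight junction claudin, fell from 47.3 ± 2.57 to 8.06 ± 0.130 CPM. Ttyh1, Slco2b1, Nrxn2 and Fry had log2 fold changes of -3.17 ± 0.10, -2.77 ± 0.12, -2.73 ± 0.11 and -2.36 ± 0.20. Rtl8a (-2.88 ± 0.21), Rtl8b (-2.77 ± 0.22) and Speer4a (-2.44 ± 0.12) are uncertain because near copies can share their reads. The naming rule required that the 3 samples of either group did not overlap, so this is no check on these genes.

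Of the interferon response genes 26 of 28 measured members rose and 0 fell. In the interferon list 27 rose and 0 fell adjusted over the list alone (camera adjusted p = 2.3e-22, adjusted p = 7.3e-04 with an estimated correlation). Usp18, which limits interferon signalling, rose from 8.17 ± 0.556 to 72.6 ± 1.22 CPM. Oas2, a sensor of double-stranded RNA, rose from 0.470 ± 0.174 to 10.9 ± 0.563 CPM. Of the NF-kB and inflammatory genes 18 of 23 measured members rose and 0 fell. In the NF-kB list 19 rose and 0 fell adjusted over the list alone (camera adjusted p = 5.7e-17, adjusted p = 9.6e-04 with an estimated correlation). Among them the neutrophil chemokine Cxcl1 rose from 6.92 ± 1.07 to 340.4 ± 7.34 CPM. Its relative Cxcl2 rose from 1.73 ± 0.415 to 71.7 ± 1.62 CPM. Of the YAP/TAZ-TEAD targets 10 of 20 measured members rose and 0 fell, or 16 and 0 without TAZ-CAMTA1 replicate 2. In the YAP/TAZ-TEAD list 11 rose and 0 fell adjusted over the list alone (camera adjusted p = 1.4e-07, adjusted p = 0.032 with an estimated correlation). Axl, a receptor tyrosine kinase, rose from 0.326 ± 0.107 to 12.1 ± 0.435 CPM. Of the Hippo pathway components 7 of 26 measured members rose and 1 fell, or 16 and 5 without TAZ-CAMTA1 replicate 2. In the Hippo list 7 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.0045, adjusted p = 0.53 with an estimated correlation). The risers included Wwc1, an upstream activator of the Hippo kinases (log2 fold change 1.82 ± 0.08), and the TEAD family member Tead3 (log2 fold change 1.16 ± 0.10). Vgll3, a TEAD cofactor, had 1 control read and 5.10 ± 0.0760 CPM in TAZ4A (ratio 529, 95% counting interval 79.3 to 17441).

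Of the endothelial identity genes 2 of 31 measured members rose and 17 fell. In the endothelial list 2 rose and 20 fell adjusted over the list alone (camera adjusted p = 2.7e-07, adjusted p = 0.021 with an estimated correlation). Without TAZ-CAMTA1 replicate 2 that adjusted p with an estimated correlation was 0.056. Sox18, a transcription factor of blood and lymphatic vessels, fell from 108 ± 9.92 to 22.7 ± 0.527 CPM. Clec14a, an endothelial lectin, fell from 101 ± 5.69 to 24.4 ± 0.450 CPM, while Sox7 rose (log2 fold change 0.47 ± 0.10). Of the Notch and arterial genes 1 of 12 measured members rose and 7 fell, or 2 and 9 without TAZ-CAMTA1 replicate 2. In the Notch list 2 rose and 8 fell adjusted over the list alone (camera adjusted p = 6.8e-04, adjusted p = 0.28 with an estimated correlation). The Notch ligand Dll4 fell from 311 ± 9.12 to 96.4 ± 6.17 CPM. The Notch target Nrarp fell (log2 fold change -1.23 ± 0.07), whereas the ligand Jag1 rose (log2 fold change 1.31 ± 0.19). Of the cholesterol biosynthesis genes 0 of 19 measured members rose and 13 fell, or 1 and 16 without TAZ-CAMTA1 replicate 2. In the cholesterol list 1 rose and 15 fell adjusted over the list alone (camera adjusted p = 2.7e-07, adjusted p = 0.021 with an estimated correlation). The sterol sensor Insig1 fell (log2 fold change -0.95 ± 0.06).

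Of the collagens and matrix genes 14 of 28 measured members rose and 4 fell. In the matrix list 15 rose and 4 fell adjusted over the list alone (camera adjusted p = 0.0022, adjusted p = 0.44 with an estimated correlation). Col8a1 rose from 33.2 ± 0.858 to 215 ± 4.08 CPM. Col12a1 had 1 control read and 2.42 ± 0.245 CPM in TAZ4A. The basement membrane collagen Col4a1 fell (log2 fold change -0.90 ± 0.16). Of the mesenchymal and smooth muscle genes 7 of 13 measured members rose and 1 fell, or 9 and 2 without TAZ-CAMTA1 replicate 2. In the mesenchymal list 8 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.0033, adjusted p = 0.057 with an estimated correlation). Calponin, Cnn1, had 1 control read and 7.01 ± 0.497 CPM in TAZ4A (ratio 693, 95% counting interval 109 to 23989.6). Decorin, Dcn, had 0 control reads and was at least 19.0-fold higher, against 3 reads per library. Vim, vimentin, fell (log2 fold change -0.83 ± 0.15). Of the glycolysis and hypoxia genes 9 of 24 measured members rose and 4 fell, or 15 and 6 without TAZ-CAMTA1 replicate 2. In the glycolysis list 10 rose and 4 fell adjusted over the list alone (camera adjusted p = 0.013, adjusted p = 0.080 with an estimated correlation). Hexokinase 2, Hk2, rose (log2 fold change 2.55 ± 0.14) and Vegfa rose (log2 fold change 1.51 ± 0.12), while Ndrg1 fell (log2 fold change -1.24 ± 0.07). Of the stress response genes 8 of 20 measured members rose and 1 fell, or 13 and 3 without TAZ-CAMTA1 replicate 2. In the stress response list 10 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.0045, adjusted p = 0.47 with an estimated correlation). Sesn2, an inhibitor of growth signalling, and Chac1, which degrades glutathione, rose (log2 fold changes 1.09 ± 0.08 and 0.93 ± 0.12). Of the MAPK feedback and immediate-early genes 5 of 26 measured members rose and 10 fell, or 7 and 16 without TAZ-CAMTA1 replicate 2. In the MAPK list 6 rose and 12 fell adjusted over the list alone (camera adjusted p = 0.024, adjusted p = 0.095 with an estimated correlation). The transcription factor genes Fosb and Egr2 fell (log2 fold changes -2.16 ± 0.14 and -1.34 ± 0.12), and Ier3 rose (log2 fold change 1.15 ± 0.14). The MAPK list's call was lost with quantile normalization (adjusted p = 0.0954). Of the mitochondrially encoded genes, which have nuclear copies that can share reads, 0 of 8 measured members rose and 4 fell. In the mitochondrial list 0 rose and 5 fell adjusted over the list alone (camera adjusted p = 0.031, adjusted p = 0.28 with an estimated correlation). That list's call was lost without control replicate 3 (adjusted p = 0.0502), TAZ4A replicate 2 (0.0514) or TAZ-CAMTA1 replicate 2 (0.0552), and with quantile normalization (0.0982).

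The other lists did not pass against the rest of the genes, and are given by their members that passed as single genes. Venous and lymphatic genes had 2 up and 1 down of 7 measured, or 4 and 1 without TAZ-CAMTA1 replicate 2 (3 and 1 adjusted over the list alone, list adjusted p = 0.31). Angiogenic ligands and tip cell genes had 9 up and 5 down of 18 measured (10 and 5 adjusted over the list alone, list adjusted p = 0.22). Matrix proteases and inhibitors had 5 up and 4 down of 16 measured, or 8 and 7 without TAZ-CAMTA1 replicate 2 (7 and 4 adjusted over the list alone, list adjusted p = 0.36). Actin and focal adhesion genes had 2 up and 6 down of 26 measured, or 8 and 9 without TAZ-CAMTA1 replicate 2 (2 and 6 adjusted over the list alone, list adjusted p = 0.61). TGF-beta and BMP response had 5 up and 4 down of 17 measured, or 6 and 9 without TAZ-CAMTA1 replicate 2 (5 and 6 adjusted over the list alone, list adjusted p = 0.92). Cell cycle genes had 2 up and 5 down of 38 measured, or 4 and 13 without TAZ-CAMTA1 replicate 2 (2 and 4 adjusted over the list alone, list adjusted p = 0.34). P53 target genes had 7 up and 1 down of 19 measured, or 8 and 4 without TAZ-CAMTA1 replicate 2 (7 and 1 adjusted over the list alone, list adjusted p = 0.064). The p53 list passed as higher with quantile normalization (adjusted p = 0.00992). Nuclear-encoded respiratory chain genes had 0 up and 0 down of 25 measured, or 5 and 3 without TAZ-CAMTA1 replicate 2 (0 and 0 adjusted over the list alone, list adjusted p = 0.95). Replication-dependent histones had 0 up and 0 down of 3 measured, or 1 and 1 without TAZ-CAMTA1 replicate 2 (1 and 1 adjusted over the list alone, list adjusted p = 0.92). The proliferation gene Ccnd1 rose (log2 fold change 0.79 ± 0.07), and the replication licensing gene Mcm6 fell (log2 fold change -0.65 ± 0.07). Among lists of other cell types, epithelial markers had 4 up and 1 down of 7 measured, or 4 and 2 without TAZ-CAMTA1 replicate 2 (4 and 2 adjusted over the list alone, list adjusted p = 0.077). The keratin gene Krt19 rose from 0.493 ± 0.0602 to 8.76 ± 1.02 CPM. Blood cell markers had 1 up and 0 down of 4 measured, or 2 and 2 without TAZ-CAMTA1 replicate 2 (1 and 0 adjusted over the list alone, list adjusted p = 0.66). Pancreatic acinar and islet markers had 0 up and 0 down of 1 measured (0 and 0 adjusted over the list alone, list adjusted p = 0.61). Neuronal markers had 2 up and 1 down of 6 measured, or 2 and 3 without TAZ-CAMTA1 replicate 2 (2 and 1 adjusted over the list alone, list adjusted p = 0.83). The median, the mean and the test differed in sign for the TGF-beta and BMP response (median -0.23, mean 0.22, test down) and for the respiratory chain (median -0.03, mean -0.01, test up).

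By limma at an adjusted p under 0.05, 1718 of 13346 genes were higher and 1507 lower in the libraries labelled TAZ4A than in control, and in 8235 genes (61.7%, against 10% by chance) the samples of the groups did not overlap. The authors' deposited table listed 2110 genes higher and 1252 lower at a false discovery rate under 0.05 among 23744. Of the authors' calls 2669 were among the 13346 genes tested here. Of these, 2472 were called here in the same direction and 0 in the opposite one. With CPM rescaled to the same sum in every library the split became 2077 higher and 1179 lower (63.8% higher, against 53.3%), with TPM 1741 and 1052 (62.3%), and with quantile normalization 1540 and 1656 (48.2%). Rescaling put the median of all genes at 0.05 on the log2 scale against -0.01. The count depended on the libraries in the fit, with 3637 higher and 3824 lower without TAZ-CAMTA1 replicate 2, and 986, 994 and 990 lower without control replicate 1, 2 or 3, or 941, 949 and 927 without TAZ4A replicate 1, 2 or 3.

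The second comparison asked what the fusion changes, as TAZ-CAMTA1 against control. Inflammatory and glycolytic genes were higher in TAZ-CAMTA1, and cholesterol synthesis and cell cycle genes were lower. Bnip3, a mitophagy gene induced by low oxygen, rose from 17.1 ± 1.01 to 97.9 ± 9.43 CPM (log2 fold change 2.48 ± 0.09, adjusted p = 8.9e-07). Insig1, a sterol sensor, fell from 162 ± 3.63 to 28.6 ± 0.934 CPM (log2 fold change -2.48 ± 0.06, adjusted p = 1.3e-07). Ankrd1 rose from 30.1 ± 1.64 to 104 ± 5.69 CPM (log2 fold change 1.77 ± 0.07, adjusted p = 1.8e-06).

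By the same rule the 10 largest rises were Lcn2, Prnd, Ddr2, C3, Steap4, Lcp2, Cxcl1, Prg2, Lyz2 and Serpina3g. Lcn2 rose from 3.52 ± 0.862 to 209 ± 65.0 CPM. Ddr2, a receptor kinase for collagen, rose from 3.65 ± 0.246 to 121 ± 42.4 CPM. Prnd, the prion-like protein Doppel, rose from 1.02 ± 0.195 to 58.6 ± 6.73 CPM. C3 rose from 1.96 ± 0.0859 to 50.6 ± 6.85 CPM. Steap4, a metalloreductase, had 3 control reads and 10.8 ± 3.12 CPM in TAZ-CAMTA1 (ratio 273, 95% counting interval 106 to 1508). Lcp2 and Prg2 had log2 fold changes of 4.33 ± 0.08 and 3.97 ± 0.20. Serpina3g (3.50 ± 0.07) and Lyz2, with 2 control reads and 7.73 ± 2.33 CPM in TAZ-CAMTA1, are uncertain because near copies can share their reads. Among the 10 largest falls were Ptgs2, Nr4a2, Alcam, Fam198b, Cmklr1, Insig1, Fam180a, Pde7b and Nqo1. Ptgs2, the inducible cyclooxygenase, fell from 59.8 ± 3.60 to 6.67 ± 2.44 CPM. The oxidoreductase gene Nqo1 fell from 276 ± 5.98 to 62.4 ± 7.09 CPM. Nr4a2, Alcam, Fam198b, Cmklr1, Fam180a and Pde7b had log2 fold changes of -3.06 ± 0.16, -2.63 ± 0.10, -2.55 ± 0.13, -2.49 ± 0.23, -2.42 ± 0.12 and -2.31 ± 0.29. By the naming rule the 3 samples of either group did not overlap.

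Of the cholesterol biosynthesis genes 0 of 19 measured members rose and 17 fell. In the cholesterol list 0 rose and 17 fell adjusted over the list alone (camera adjusted p = 2.4e-11, adjusted p = 0.0068 with an estimated correlation). Insig1 was among the members that fell. Of the glycolysis and hypoxia genes 19 of 24 measured members rose and 1 fell. In the glycolysis list 19 rose and 1 fell adjusted over the list alone (camera adjusted p = 1.1e-08, adjusted p = 0.0068 with an estimated correlation). Without TAZ-CAMTA1 replicate 2 that adjusted p with an estimated correlation was 0.0504. The hexokinase gene Hk2 rose from 5.32 ± 0.714 to 18.3 ± 3.00 CPM. Of the NF-kB and inflammatory genes 15 of 23 measured members rose and 2 fell. In the NF-kB list 16 rose and 2 fell adjusted over the list alone (camera adjusted p = 4.4e-07, adjusted p = 0.0068 with an estimated correlation). Cxcl1 rose from 6.92 ± 1.07 to 144 ± 19.1 CPM. Cxcl2 rose (log2 fold change 3.49 ± 0.13), while Selp, P-selectin, fell (log2 fold change -0.81 ± 0.11). Of the cell cycle genes 0 of 38 measured members rose and 17 fell, or 1 and 31 without TAZ-CAMTA1 replicate 2. In the cell cycle list 0 rose and 19 fell adjusted over the list alone (camera adjusted p = 3.0e-06, adjusted p = 0.0068 with an estimated correlation). The mitotic kinase Plk1 fell from 135 ± 5.12 to 84.2 ± 8.09 CPM. Of the stress response genes 1 of 20 measured members rose and 11 fell, or 1 and 19 without TAZ-CAMTA1 replicate 2. In the stress response list 1 rose and 13 fell adjusted over the list alone (camera adjusted p = 9.4e-05, adjusted p = 0.37 with an estimated correlation). The chaperone Hspa5 fell from 1273 ± 87.8 to 737 ± 47.2 CPM. The serine synthesis gene Phgdh fell (log2 fold change -1.41 ± 0.15), while the transcription factor Atf3 rose (log2 fold change 0.83 ± 0.08).

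Of the collagens and matrix genes 13 of 28 measured members rose and 2 fell, or 21 and 2 without TAZ-CAMTA1 replicate 2. In the matrix list 14 rose and 2 fell adjusted over the list alone (camera adjusted p = 1.3e-04, adjusted p = 0.37 with an estimated correlation). Col6a3 rose from 2.65 ± 0.530 to 25.7 ± 9.06 CPM. Col18a1, whose protein gives rise to endostatin, rose (log2 fold change 1.99 ± 0.14). Of the angiogenic ligands and tip cell genes 9 of 18 measured members rose and 2 fell, or 12 and 4 without TAZ-CAMTA1 replicate 2. In the angiogenic list 10 rose and 2 fell adjusted over the list alone (camera adjusted p = 0.0021, adjusted p = 0.14 with an estimated correlation). Angptl4, a secreted inhibitor of lipoprotein lipase, rose from 16.5 ± 1.77 to 85.2 ± 19.2 CPM. Nid2, a basement membrane nidogen, rose from 0.889 ± 0.0748 to 8.11 ± 1.28 CPM. Of the actin and focal adhesion genes 8 of 26 measured members rose and 1 fell, or 16 and 5 without TAZ-CAMTA1 replicate 2. In the actin list 8 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.033, adjusted p = 0.44 with an estimated correlation). The integrin gene Itgb5 rose (log2 fold change 2.06 ± 0.10), as did the caveolin gene Cav1 (log2 fold change 0.79 ± 0.08). The list's call was lost without control replicate 2 (adjusted p = 0.0535), TAZ-CAMTA1 replicate 1 (0.0888) or TAZ-CAMTA1 replicate 3 (0.119). Of the YAP/TAZ-TEAD targets 8 of 20 measured members rose and 1 fell, or 9 and 4 without TAZ-CAMTA1 replicate 2. In the YAP/TAZ-TEAD list 8 rose and 2 fell adjusted over the list alone (camera adjusted p = 0.0496, adjusted p = 0.36 with an estimated correlation). Among them Ccn1, a matricellular protein, rose from 542 ± 10.2 to 1185 ± 27.2 CPM. That list's call was lost without control replicate 2 (adjusted p = 0.0535), TAZ4A replicate 1, 2 or 3 (0.0530, 0.0561 and 0.0528), or TAZ-CAMTA1 replicate 1 or 3 (0.0930 and 0.112). It was also lost with the iGenomes annotation (0.0555) and with the replicate number as a block (0.0786). Of 6 measured neuronal markers, 15 having been listed, 3 rose and 0 fell. In the neuronal list 3 rose and 0 fell adjusted over the list alone (camera adjusted p = 0.033, adjusted p = 0.16 with an estimated correlation). Gap43, a protein of growth cones, rose from 12.4 ± 0.671 to 44.7 ± 7.81 CPM. That list's call was lost without TAZ-CAMTA1 replicate 1 (adjusted p = 0.0625) or 3 (0.0552), with quantile normalization (0.0663) and with the iGenomes annotation (0.0861).

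The other lists did not pass against the rest of the genes. Interferon response genes went both ways, as 8 rose and 13 fell of 28 (8 and 16 adjusted over the list alone, list adjusted p = 0.057). This list passed as lower without TAZ-CAMTA1 replicate 2 (adjusted p = 0.041) or without control replicate 3 (0.0498), in a range of 0.041 to 0.091 with single libraries left out. Ifit1 fell from 65.7 ± 2.97 to 22.1 ± 1.29 CPM. Ifi44 fell (log2 fold change -1.86 ± 0.10), while the guanylate-binding protein gene Gbp2 rose (log2 fold change 0.90 ± 0.07). Endothelial identity had 6 up and 3 down of 31 measured, or 16 and 10 without TAZ-CAMTA1 replicate 2 (7 and 6 adjusted over the list alone, list adjusted p = 0.74). Sox7 rose (log2 fold change 1.23 ± 0.10) and Clec14a fell (log2 fold change -1.38 ± 0.08). Notch and arterial genes had 1 up and 3 down of 12 measured, or 4 and 4 without TAZ-CAMTA1 replicate 2 (2 and 4 adjusted over the list alone, list adjusted p = 0.77). Hippo pathway components had 3 up and 1 down of 26 measured, or 8 and 6 without TAZ-CAMTA1 replicate 2 (3 and 0 adjusted over the list alone, list adjusted p = 0.64). Venous and lymphatic genes had 3 up and 3 down of 7 measured (3 and 3 adjusted over the list alone, list adjusted p = 0.67). Matrix proteases and inhibitors had 6 up and 4 down of 16 measured (6 and 5 adjusted over the list alone, list adjusted p = 0.19). TGF-beta and BMP response had 5 up and 4 down of 17 measured, or 8 and 6 without TAZ-CAMTA1 replicate 2 (5 and 5 adjusted over the list alone, list adjusted p = 0.77). Mesenchymal and smooth muscle genes had 5 up and 1 down of 13 measured, or 7 and 2 without TAZ-CAMTA1 replicate 2 (5 and 1 adjusted over the list alone, list adjusted p = 0.16). They passed as higher without TAZ-CAMTA1 replicate 2 (adjusted p = 0.041), in a range of 0.041 to 0.19 with single libraries left out. MAPK feedback and immediate-early genes had 8 up and 14 down of 26 measured (8 and 14 adjusted over the list alone, list adjusted p = 0.35). Of these the transcription factor gene Egr1 rose (log2 fold change 1.37 ± 0.08) and the feedback phosphatase gene Dusp6 fell (log2 fold change -1.11 ± 0.07). P53 target genes had 2 up and 8 down of 19 measured, or 5 and 10 without TAZ-CAMTA1 replicate 2 (4 and 8 adjusted over the list alone, list adjusted p = 0.31). Replication-dependent histones had 0 up and 0 down of 3 measured, or 0 and 2 without TAZ-CAMTA1 replicate 2 (0 and 0 adjusted over the list alone, list adjusted p = 0.44). Mitochondrially encoded genes had 0 up and 3 down of 8 measured, or 1 and 3 without TAZ-CAMTA1 replicate 2 (0 and 3 adjusted over the list alone, list adjusted p = 0.44). Epithelial markers had 3 up and 0 down of 7 measured (3 and 0 adjusted over the list alone, list adjusted p = 0.088). Blood cell markers had 1 up and 0 down of 4 measured, or 2 and 1 without TAZ-CAMTA1 replicate 2 (2 and 0 adjusted over the list alone, list adjusted p = 0.14). Pancreatic acinar and islet markers had 1 up and 0 down of 1 measured (1 and 0 adjusted over the list alone, list adjusted p = 0.099).

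The nuclear-encoded respiratory chain genes had 0 up and 1 down of 25 measured (0 and 0 adjusted over the list alone, list adjusted p = 0.83). They turned to lower without TAZ-CAMTA1 replicate 2, with 14 members down (adjusted p = 0.018, in a range of 0.018 to 0.92 with single libraries left out). The median and the mean of the TGF-beta and BMP response differed in sign (median -7.9e-04, mean 0.20, test up).

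By limma, 2153 of 13346 genes were higher and 1987 lower in TAZ-CAMTA1 than in control, and in 6180 genes (46.3%, against 10% by chance) the samples of the groups did not overlap. The authors' deposited table listed 2253 genes higher and 1542 lower among 23744. Of the authors' calls 3338 were among the 13346 genes tested here. Of these, 3113 were called here in the same direction and 0 in the opposite one. With CPM rescaled to the same sum in every library 59.1% of the called genes were higher, against 52.0%. The counts were 3637 higher and 4166 lower without TAZ-CAMTA1 replicate 2, and 1212 and 1166 lower without control replicate 2 or 3.

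**Figure D3:**
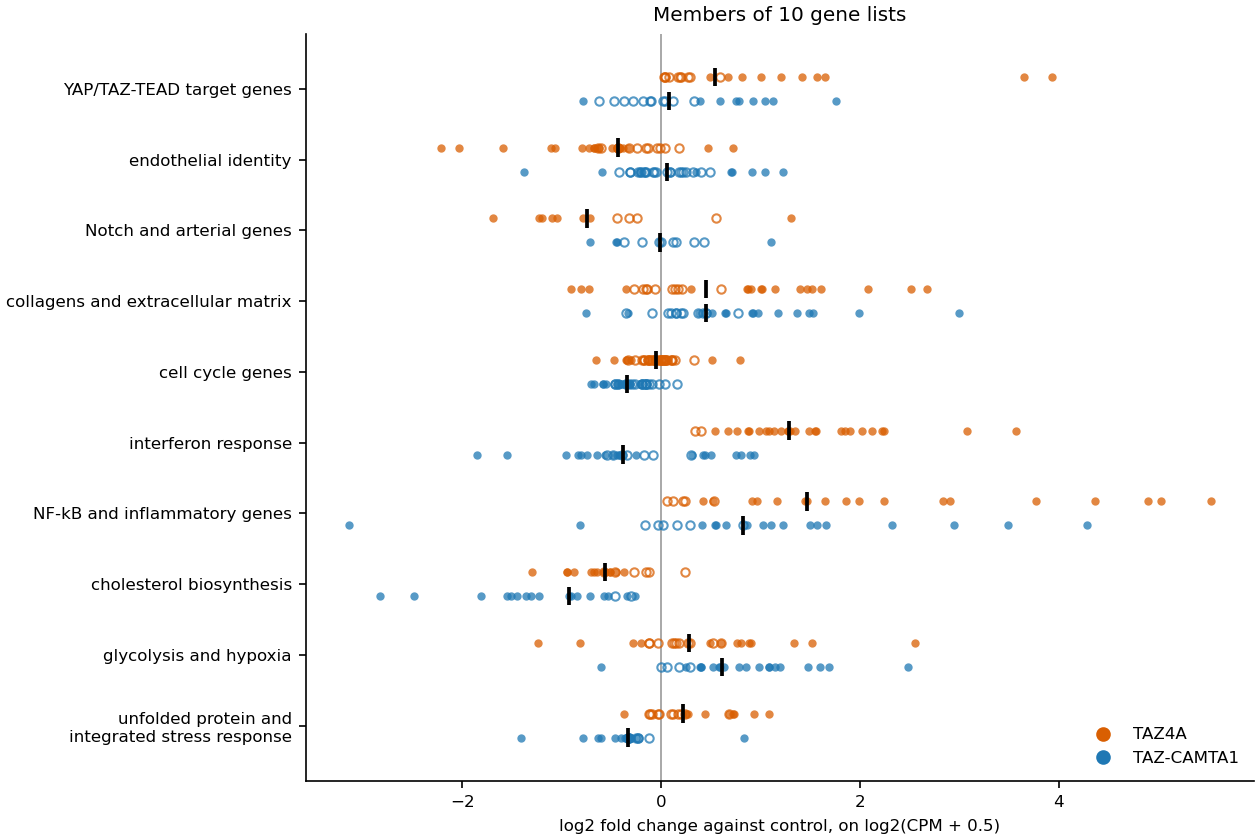
Log2 fold changes against control of the measured members of 10 gene lists, for TAZ4A and for TAZ-CAMTA1. Each point is a gene, filled where its adjusted p was under 0.05 and open where not, with the list median as a black tick. The interferon response list has 26 members up for TAZ4A against control, and 8 up and 13 down for TAZ-CAMTA1 against control.

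The third comparison set TAZ-CAMTA1 against the libraries labelled TAZ4A, which is the contrast named in the title of the series. Interferon response, inflammatory and cell cycle genes were lower in TAZ-CAMTA1, and endothelial identity genes were higher. Sox18 rose from 22.7 ± 0.527 to 144 ± 28.5 CPM (log2 fold change 2.62 ± 0.14, adjusted p = 3.1e-06). Dll4 rose from 96.4 ± 6.17 to 311 ± 17.1 CPM (log2 fold change 1.68 ± 0.08, adjusted p = 1.4e-06). Ankrd1 fell from 385 ± 2.15 to 104 ± 5.69 CPM (log2 fold change -1.89 ± 0.07, adjusted p = 4.7e-07). Ifi44, an interferon-induced gene, fell from 74.0 ± 2.02 to 6.56 ± 0.804 CPM (log2 fold change -3.41 ± 0.10, adjusted p = 1.3e-07).

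By the same rule the 10 largest rises were Gpihbp1, Rnase1, Prg2, Pi16, Sema7a, Kcne3, Tspan18, Slco2b1, Cxcr4 and Speer4a. Gpihbp1, which anchors lipoprotein lipase on capillary endothelium, rose from 27.6 ± 0.837 to 312 ± 119 CPM. Rnase1, an endothelial ribonuclease, rose from 9.38 ± 0.979 to 97.8 ± 23.2 CPM. Cxcr4 rose from 26.3 ± 0.931 to 188 ± 15.9 CPM. The semaphorin Sema7a rose (log2 fold change 3.05 ± 0.12). Prg2, Pi16, Kcne3, Tspan18 and Slco2b1 had log2 fold changes of 3.20 ± 0.20, 3.06 ± 0.16, 2.87 ± 0.10, 2.85 ± 0.15 and 2.83 ± 0.12, and Speer4a (2.76 ± 0.12) is uncertain because of near copies. The 10 largest falls were Siglecg, Sema3c, Fam198b, Oas3, Ptprq, Ccl20, Msln, Oas2, Iigp1 and Aldh1a1. Fam198b fell from 148 ± 2.81 to 3.68 ± 0.796 CPM. Oas3, a relative of Oas2, fell from 52.7 ± 1.27 to 1.30 ± 0.522 CPM. Mesothelin, Msln, fell from 17.7 ± 0.893 to 0.440 ± 0.0233 CPM. Ptprq, a receptor phosphatase, had 0 reads in TAZ-CAMTA1 and 11.1 ± 0.573 CPM in TAZ4A, at least 107-fold lower, against 3 reads per library. Siglecg, Ccl20 and Aldh1a1 had 3, 3 and 2 reads in TAZ-CAMTA1 and 22.9 ± 0.199, 10.3 ± 0.229 and 8.09 ± 0.363 CPM in TAZ4A. Sema3c, Oas2 and Iigp1 stood at 0.0412 ± 0.0357, 0.116 ± 0.0734 and 1.62 ± 0.357 CPM in TAZ-CAMTA1 and 19.1 ± 1.46, 10.9 ± 0.563 and 35.0 ± 1.41 CPM in TAZ4A. Here too the naming rule required that the 3 samples of either group did not overlap.

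**Figure D4:**
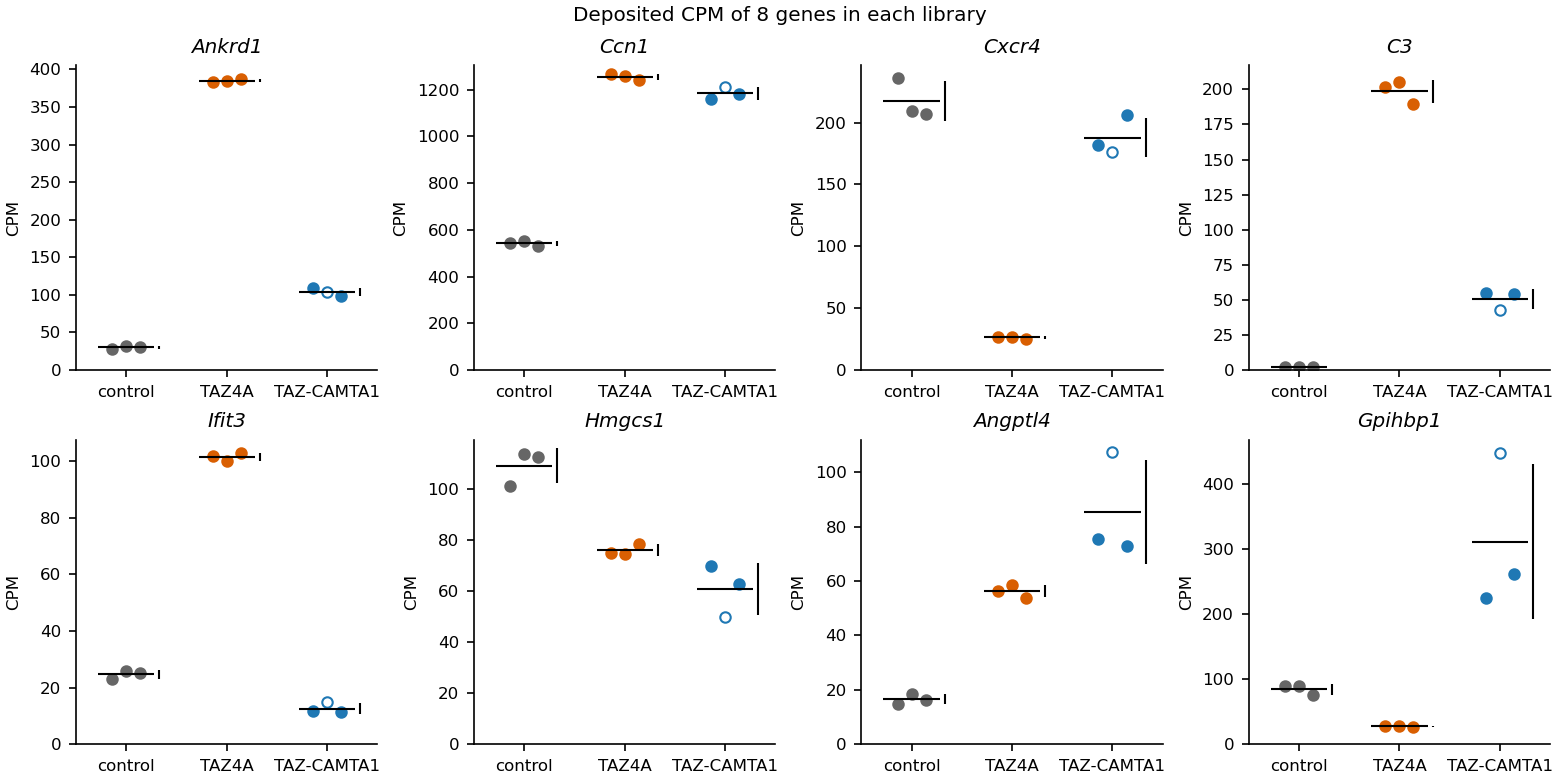
Deposited CPM of 8 genes in the 9 libraries by group on a linear axis, each point a library (open circle, TAZ-CAMTA1 replicate 2), with the group mean as a black bar and the SD as a vertical line. Ankrd1 stood at 30.1, 385 and 104 CPM in control, TAZ4A and TAZ-CAMTA1, and Cxcr4 at 217, 26.3 and 188 CPM.

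Of the interferon response genes 0 of 28 measured members rose and 26 fell. In the interferon list 0 rose and 26 fell adjusted over the list alone (camera adjusted p = 1.0e-17, adjusted p = 0.0014 with an estimated correlation). Of the endothelial identity genes 19 of 31 measured members rose and 1 fell, or 26 and 2 without TAZ-CAMTA1 replicate 2. In the endothelial list 20 rose and 1 fell adjusted over the list alone (camera adjusted p = 1.6e-06, adjusted p = 0.037 with an estimated correlation). Vwf, von Willebrand factor, rose from 2.22 ± 0.364 to 7.17 ± 1.52 CPM. Of the Notch and arterial genes 7 of 12 measured members rose and 1 fell, or 10 and 2 without TAZ-CAMTA1 replicate 2. In the Notch list 8 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.0037, adjusted p = 0.35 with an estimated correlation). The netrin receptor gene Unc5b rose from 13.9 ± 0.181 to 54.2 ± 12.9 CPM, and Jag1 fell (log2 fold change -0.97 ± 0.19). Of the YAP/TAZ-TEAD targets 1 of 20 measured members rose and 11 fell, or 2 and 14 without TAZ-CAMTA1 replicate 2. In the YAP/TAZ-TEAD list 1 rose and 12 fell adjusted over the list alone (camera adjusted p = 0.0011, adjusted p = 0.11 with an estimated correlation, or 0.0430 without TAZ-CAMTA1 replicate 2). Axl fell from 12.1 ± 0.435 to 0.579 ± 0.0446 CPM. Of the Hippo pathway components 1 of 26 measured members rose and 8 fell, or 4 and 16 without TAZ-CAMTA1 replicate 2. In the Hippo list 1 rose and 8 fell adjusted over the list alone (camera adjusted p = 0.0032, adjusted p = 0.50 with an estimated correlation). Wwc1 fell from 78.9 ± 1.72 to 19.0 ± 1.28 CPM. Of the NF-kB and inflammatory genes 4 of 23 measured members rose and 11 fell. In the NF-kB list 4 rose and 12 fell adjusted over the list alone (camera adjusted p = 0.0011, adjusted p = 0.044 with an estimated correlation). That adjusted p with an estimated correlation was 0.060 without TAZ-CAMTA1 replicate 2. Ptgs2 fell from 86.7 ± 3.24 to 6.67 ± 2.44 CPM, while the NF-kB subunit gene Relb rose (log2 fold change 0.88 ± 0.18). Of the cell cycle genes 1 of 38 measured members rose and 14 fell, or 1 and 28 without TAZ-CAMTA1 replicate 2. In the cell cycle list 1 rose and 14 fell adjusted over the list alone (camera adjusted p = 7.4e-04, adjusted p = 0.037 with an estimated correlation). The mitotic transcription factor gene Foxm1 fell (log2 fold change -0.89 ± 0.13) and Mcm6 rose (log2 fold change 0.46 ± 0.07).

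Of the stress response genes 1 of 20 measured members rose and 15 fell. In the stress response list 1 rose and 16 fell adjusted over the list alone (camera adjusted p = 1.3e-06, adjusted p = 0.25 with an estimated correlation). Sesn2 fell (log2 fold change -1.43 ± 0.08). Of the p53 targets 1 of 19 measured members rose and 9 fell, or 2 and 14 without TAZ-CAMTA1 replicate 2. In the p53 list 1 rose and 9 fell adjusted over the list alone (camera adjusted p = 0.0037, adjusted p = 0.11 with an estimated correlation, or 0.0485 without TAZ-CAMTA1 replicate 2). Ccng1, cyclin G1, fell from 270.3 ± 3.87 to 96.3 ± 13.8 CPM. The antiproliferative gene Btg2 rose from 74.2 ± 2.38 to 228 ± 10.9 CPM. Of the cholesterol biosynthesis genes 1 of 19 measured members rose and 11 fell, or 2 and 14 without TAZ-CAMTA1 replicate 2. In the cholesterol list 1 rose and 12 fell adjusted over the list alone (camera adjusted p = 7.4e-04, adjusted p = 0.083 with an estimated correlation, or 0.0430 without TAZ-CAMTA1 replicate 2). Insig1 fell from 83.8 ± 0.625 to 28.6 ± 0.934 CPM. Of the glycolysis and hypoxia genes 7 of 24 measured members rose and 3 fell, or 11 and 4 without TAZ-CAMTA1 replicate 2. In the glycolysis list 7 rose and 3 fell adjusted over the list alone (camera adjusted p = 0.013, adjusted p = 0.083 with an estimated correlation). Bnip3 rose (log2 fold change 1.60 ± 0.09) and Hk2 fell (log2 fold change -0.86 ± 0.14). Of the actin and focal adhesion genes 11 of 26 measured members rose and 1 fell, or 17 and 2 without TAZ-CAMTA1 replicate 2. In the actin list 11 rose and 2 fell adjusted over the list alone (camera adjusted p = 0.015, adjusted p = 0.39 with an estimated correlation). This call was lost without TAZ-CAMTA1 replicate 3 (adjusted p = 0.0791) and with quantile normalization (0.0820). Integrin beta 3, Itgb3, rose (log2 fold change 1.12 ± 0.14). Of the neuronal markers 4 of 6 measured members rose and 0 fell. In the neuronal list 4 rose and 0 fell adjusted over the list alone (camera adjusted p = 0.0056, adjusted p = 0.083 with an estimated correlation).

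The other lists did not pass against the rest of the genes, though single members did. Venous and lymphatic genes had 3 up and 3 down of 7 measured (3 and 3 adjusted over the list alone, list adjusted p = 0.96). Angiogenic ligands and tip cell genes had 8 up and 4 down of 18 measured (8 and 5 adjusted over the list alone, list adjusted p = 0.12). Collagens and extracellular matrix had 8 up and 5 down of 28 measured, or 14 and 9 without TAZ-CAMTA1 replicate 2 (9 and 7 adjusted over the list alone, list adjusted p = 0.52). Col4a1 rose (log2 fold change 1.05 ± 0.16) and Col8a1 fell (log2 fold change -2.23 ± 0.20). Matrix proteases and inhibitors had 5 up and 4 down of 16 measured (5 and 4 adjusted over the list alone, list adjusted p = 0.74). Plat, tissue plasminogen activator, rose (log2 fold change 1.66 ± 0.11). Mesenchymal and smooth muscle genes had 3 up and 6 down of 13 measured, or 5 and 6 without TAZ-CAMTA1 replicate 2 (3 and 6 adjusted over the list alone, list adjusted p = 0.25). Cnn1 had 0 reads in TAZ-CAMTA1, at least 67.7-fold lower, against 3 reads per library. TGF-beta and BMP response had 6 up and 4 down of 17 measured (6 and 4 adjusted over the list alone, list adjusted p = 0.52). MAPK feedback and immediate-early genes had 12 up and 7 down of 26 measured (12 and 9 adjusted over the list alone, list adjusted p = 0.33). Replication-dependent histones had 0 up and 1 down of 3 measured, or 0 and 2 without TAZ-CAMTA1 replicate 2 (0 and 1 adjusted over the list alone, list adjusted p = 0.45). Mitochondrially encoded genes had 2 up and 0 down of 8 measured, or 4 and 0 without TAZ-CAMTA1 replicate 2 (2 and 0 adjusted over the list alone, list adjusted p = 0.33). Epithelial markers had 1 up and 3 down of 7 measured (1 and 4 adjusted over the list alone, list adjusted p = 0.45). Blood cell markers had 2 up and 0 down of 4 measured (2 and 0 adjusted over the list alone, list adjusted p = 0.11). Pancreatic acinar and islet markers had 1 up and 0 down of 1 measured (1 and 0 adjusted over the list alone, list adjusted p = 0.092). The nuclear-encoded respiratory chain genes had 0 up and 2 down of 25 measured (0 and 1 adjusted over the list alone, list adjusted p = 0.94). They turned to lower without TAZ-CAMTA1 replicate 2, with 1 member up and 14 down (adjusted p = 0.025, in a range of 0.025 to 1.00 with single libraries left out). The median, the mean and the test differed in sign for venous and lymphatic genes (median 0.15, mean -0.03, test down). The same was true of matrix proteases and inhibitors (median -0.05, mean -0.004, test up) and of the TGF-beta and BMP response (median 0.06, mean -0.02, test up).

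By limma, 2450 of 13346 genes were higher and 2440 lower in TAZ-CAMTA1 than in the libraries labelled TAZ4A, and in 7200 genes (53.9%, against 10% by chance) the samples of the groups did not overlap. The authors' deposited table listed 2447 genes higher and 2449 lower among 23744. Of the authors' calls 4206 were among the 13346 genes tested here. Of these, 3900 were called here in the same direction and 0 in the opposite one. Without TAZ-CAMTA1 replicate 2 the counts were 3893 higher and 4151 lower. TPM in place of CPM moved the median log2 fold change of all genes from -0.03 to -0.11, so that changes in TPM are to be read relative to that shift. The split in TPM was 1915 higher and 2448 lower (43.9% higher, against 50.1%).

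The responses to the 2 constructs were then set against each other. Of the genes tested, 793 were higher than control in both TAZ4A and TAZ-CAMTA1, among them C3, Lcn2, Cxcl1, Cxcl2, Ankrd1, Nid2 and Hk2, where 277 would be shared by independent lists. A further 574 were lower in both, among them Clec14a and Insig1, against 224 for independent lists. Called in opposite directions were 387, for which no number for independent lists was computed, so this count is not read as an excess. Without TAZ-CAMTA1 replicate 2 these counts were 1732, 1857 and 1323, against 991 and 1194 for independent lists. Across genes, which are not independent replicates, the log2 fold changes against control correlated with Pearson's r = 0.379 and Spearman's rho = 0.277, and 58.3% of genes had the same sign. Both comparisons use the same control libraries. In 100 draws of noise for unchanged groups with a shared simulated control, the mean r was 0.499 (0.428 to 0.578), and 66.7% had the same sign. Such an r follows from sharing a group, and the noise was that of the fit without TAZ-CAMTA1 replicate 2. In that fit the measured r was 0.432, inside the simulated range, and 62.2% of genes had the same sign. The measured r of 0.379 with all 9 libraries is therefore not read as less likeness than that of unchanged groups. The covariance with all 9 libraries was 0.114 against a simulated 0.00524, a difference of 0.109. With 3 controls, no division leaves at least 2 libraries in each part, so the controls were not split, and part of the excess of shared genes may come from the shared controls.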

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

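The library quality weights were chosen after seeing the data. Across the settings, the counts of genes stayed within 1.5 times the reported ones except in these cases. Requiring a log2 fold change of at least 1 left 646 higher and 195 lower genes (TAZ4A against control), 561 and 164 (TAZ-CAMTA1 against control) and 437 and 536 (TAZ-CAMTA1 against TAZ4A), a stricter criterion by construction. Among the 13248 genes with a length and GC content, removing a trend with length gave 4864 calls against 3212 in the first comparison, and removing both trends gave 5284, with 6304 against 4130 in the second. Fitting only the 6 samples compared gave 3673 and 3862 in the first comparison, without the spread of TAZ-CAMTA1 replicate 2, and 1042 lower in the second. The quality weights gave 3741 and 3971, 3448 and 3948, and 4044 and 4368, with a weight of 0.0318 for that library. Leaving out single libraries gave 1241 to 3637 higher and 927 to 3824 lower, 1552 to 3637 and 1166 to 4166, and 1687 to 3893 and 1644 to 4151. The highest value of each range came without TAZ-CAMTA1 replicate 2.

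Wwtr1 in TAZ4A against control was -0.698 with TPM, no longer past the threshold (adjusted p = 0.054, with 1.1e-10 to 0.054 over all alternatives), and the cause was not tested. Wwtr1 in TAZ-CAMTA1 against control ranged from -0.474 to -0.168 with libraries left out, and was -0.176 with quality weights (adjusted p = 0.011, 0.0053 to 0.23 over all alternatives). In TAZ-CAMTA1 against TAZ4A it ranged from 0.285 to 0.590, with 0.594 under quality weights and 0.401 under quantile normalization, past the threshold in both. Tead1 in TAZ-CAMTA1 against control turned from -0.199 to 0.160 without TAZ-CAMTA1 replicate 2 (range -0.385 to 0.160), and the respiratory chain list turned to lower without it, with adjusted p from 0.0183 to 0.922 in TAZ-CAMTA1 against control and from 0.0250 to 1.00 against TAZ4A. Estimated correlations left 5, 4 and 4 lists of 13, 10 and 13, and single libraries left 12 to 13, 7 to 13 and 12 to 14. The cause was not tested for these lists, Tead1 or the respiratory chain. The correlation of the responses was 0.327 to 0.432 with a library left out. Of the named genes 257 were the same and 23 fell short with TPM, and 276 and 1 without TAZ-CAMTA1 replicate 2, where 10 more passed, among them Tead1 with its direction turned. Without control replicates 1 to 3, 20, 20 and 21 fell short, without TAZ4A replicates 1 to 3, 23, 24 and 24, and without TAZ-CAMTA1 replicates 1 and 3, 5 and 7.

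Replicate numbers are shared between groups, and the evidence that they pair the samples was mixed. Deviations of same-numbered samples correlated at -0.280 to 0.464 over 9 pairs, 6 of them over 0.1, and 6 of 9 correlated best with their own number. With the number as a block the counts were 1641 and 1415, 2099 and 1916, and 2418 and 2383, and the YAP/TAZ-TEAD list in TAZ-CAMTA1 against control did not pass (adjusted p = 0.0786). Of the named genes 285 were the same with the block and 2 did not pass. edgeR on the recovered reads called 1767 and 1471, 2368 and 1683, and 2697 and 2167 genes. Of 67 simulated changes by a factor of 1.5, 18, 23 and 12 were recovered (26.9%, 34.3% and 17.9%). Differences between these rates may reflect the draw, and depth was not varied.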

Other observations

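Tests chosen only after the result was seen were those of a mislabelled sample, of length as the whole cause, of reads lost from the coding part, of swapped labels and of the vector preparation.

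Among the genes that moved in opposite directions under the constructs, Fam198b stood at 23.7 ± 1.49 CPM in control, 148 ± 2.81 CPM in the libraries labelled TAZ4A (log2 fold change 2.62 ± 0.13, adjusted p = 2.0e-06), and at 3.68 ± 0.796 CPM in TAZ-CAMTA1 (log2 fold change -2.55 ± 0.13, adjusted p = 4.9e-06). Bmper, a modulator of BMP signalling, rose in TAZ4A (log2 fold change 1.97 ± 0.12, adjusted p = 8.2e-06) and fell in TAZ-CAMTA1 (log2 fold change -1.41 ± 0.12, adjusted p = 8.3e-05). Ifit1, an interferon-induced gene, likewise rose in TAZ4A (log2 fold change 1.08 ± 0.07, adjusted p = 1.3e-05) and fell in TAZ-CAMTA1 (log2 fold change -1.55 ± 0.07, adjusted p = 3.2e-06). The tight junction gene Cldn4 rose in TAZ-CAMTA1 against control (log2 fold change 1.67 ± 0.14, adjusted p = 7.7e-05). Its fall in TAZ4A (log2 fold change -0.47 ± 0.14, adjusted p = 0.043) did not pass without 7 of the 9 libraries, each left out in turn. Plat, tissue plasminogen activator, was at 489 ± 77.3 CPM in TAZ-CAMTA1, against 261 ± 6.74 CPM in control. The matrix metalloproteinase gene Mmp2 rose in both, from 9.74 ± 0.217 CPM in control to 48.8 ± 1.33 and 41.3 ± 3.12 CPM (log2 fold change 2.27 ± 0.08, adjusted p = 1.9e-07, and log2 fold change 2.03 ± 0.08, adjusted p = 1.0e-06). Bmper, Cldn4, Plat and Mmp2 belong to lists that did not pass as lists, and the list of Ifit1 did not pass in TAZ-CAMTA1 against control. All of these genes were singled out after their values were seen.

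TAZ-CAMTA1 replicate 2 differed from its group mates by gene length, with median log2 deviations of 0.46, 0.13, -0.16 and -0.62 from the shortest to the longest of 4 equal sets of transcripts. A mislabelled sample is argued against by its 51 reads across Camta1 exons 9 to 24, absent from the other groups. A trend with GC content is argued against as the whole source, since removing it left the correlation with its mates at 0.973. Removing it took away 14.1% of the variance of the deviation, so a part for GC content stays open. A trend with length as the whole cause is argued against since 0.471 remained as the SD of its deviation (0.218 between its mates). A length-related loss of longer RNA, as with degraded or differently prepared RNA, may be part of the cause, as removing the length trend brought the correlation to 0.982 and took away 40.5% of the variance, between the bounds set in advance. No biological explanation was tested, since the difference lies within a group.

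Wwtr1 was lower in the libraries labelled TAZ4A. Reads lost from the coding part carried by the construct are argued against by the exon 1 to 2 junction, outside it, where the ratio to control was 0.537, and swapped labels by the 10 YAP/TAZ-TEAD targets that were higher there. The authors' normalization is argued against as the source, because the log2 fold change was -0.698 (adjusted p = 0.0078) with CPM rescaled to the same sum in every library, although TPM ended the call at -0.70 against -0.76 ± 0.15, within that error, by a larger adjusted p (0.054). An effect of the construct on the endogenous gene stays open and was not tested.

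Interferon response genes were higher in the libraries labelled TAZ4A than in both other groups. Blood cells in the cultures are argued against as the direct source of these reads. Ptprc, Laptm5 and Csf1r, with Tyrobp absent from the gene table and counted as 0, together reached 0.175 CPM. This was 0.00974% of the summed gain of 1797 CPM. Lyz2, another listed blood cell marker, had 2 control reads and 1.70 ± 0.421 CPM in TAZ4A, though near copies can share its reads. Whether a few blood cells acted on the other cells was not tested. A single library is argued against because, with a TAZ4A library left out, the lowest count of members that were higher was 23. A response to the vector preparation of these cells cannot be told apart from an effect of TAZ4A, because each construct was delivered by its own vector, and the 26 members that rose in TAZ4A against control go with either. Both may hold.

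Dividing the 6 samples of a comparison in other ways gives 10 splits, too few for a share under 0.05. In each of the 3 comparisons 1 split, the real one, reached the number of genes called (3225, 4140 and 4890), where the highest other split called 0. For the gene lists, 1, 3 and 1 splits reached the real number (13, 10 and 13), and the highest of the others called 10, 11 and 8.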
